A study of Mus musculus with 6 samples.

How the data were processed

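Bright and medium Id4-GFP germ cells from 10-day-old male C57BL/6 mice were profiled in 3 Dnmt3A WT/WT and 3 KO/KO samples. Per the labels' protocols, RNA was extracted with a PicoPure kit, treated with DNase and made into libraries with a SMARTer stranded total RNA kit. The deposited files hold raw read counts per feature, made by the authors with STAR 2.7.0a and featureCounts 1.5.1 on mm10, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads with several positions are not given in the sources used here, so counts of overlapping genes, near-identical copies and repeat families carry that uncertainty.

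Each file has 55292 rows, of which 54087 are genes and 1205 are transposable element families. Gene rows summed to between 42681201 and 61749155 counts per library, and the 5 most abundant rows, ribosomal RNA among them, took between 25.0% and 29.9% of these. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom between libraries of 1 genotype was between 12.4 and 14.8 in WT/WT and between 36.3 and 49.2 in KO/KO. Between genotypes it was between 34.5 and 35.4 for KO/KO replicate 1 and between 69.7 and 90.0 for KO/KO replicates 2 and 3, so by this measure KO/KO replicate 1 lay as near to the WT/WT libraries as to the other KO/KO libraries. On the first principal component, which held 51.8% of the variance, the WT/WT libraries lay at -48.7, -48.5 and -54.2 and the KO/KO libraries at 29.2, 57.6 and 64.5.

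Gene counts were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM factors, the filterByExpr filter and genotype as the only term. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. CPM were computed from the gene totals and TMM factors, and the standard error of a log2 fold change was derived here as its size divided by the square root of F. Gene lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the 24 lists with at least 3 tested members. The same test with an estimated correlation called none of the lists, and fry called 8, which are not the same 8.

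The test, the samples, 25 gene lists and the rule for named genes were fixed before the data were examined. The rule takes Dnmt3a, the 12 largest rises and 12 largest falls among called genes with an average log2 CPM of at least 1 and fully separated genotypes, leaving out predicted and clone symbols, and up to 4 members per list with the smallest p. Other genes were named after their values were seen. Another 7 lists, and the test of the transposable element families, were chosen after the data were seen, the latter when the counts of families from several fits were already known. The camera p-values of these 7 lists were adjusted over the 7 lists alone. The families were fitted together with the genes, using the gene totals and factors, and adjusted over the families alone, because the prior degrees of freedom were 5.89 in that fit and 74.6 when the families were fitted alone, which pools their spread almost completely. All settings tried for the families are given in the closing section.

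The fits were tested on simulated data with the means, library sizes and spread of these libraries, in 5 draws. In each draw 200 genes or 40 families were changed, and both genotypes had the same spread. For the genes, 49.9% of 2-fold and 83.5% of 4-fold changes were recovered and 9.82% of the calls were false. For the families, 72.0% of 2-fold and all 4-fold changes were recovered and 4.89% of the calls were false. In the first draw none of 24 random lists was called, but with genes drawn independently this does not test lists of correlated members.

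Alternatives were RLE and upper quartile factors, no filter and a filter at 1 CPM in 3 libraries, leaving out each library, replicate number as a block, DESeq2 1.42.0, limma-voom, other thresholds and other list tests. Coordinates and exon overlaps came from GENCODE M21 on GRCm38, the same assembly as mm10, in which 28418 gene symbols were found directly and 250 through RefSeq synonyms. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.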

Results

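RNA was measured in 6 libraries of male germ cells from C57BL/6 mice at 10 days post partum. The cells were sorted for bright and medium fluorescence of an Id4-GFP reporter, a gate that the labels describe as approximating spermatogonial stem cells, the cells from which sperm production is renewed. Of the 6 libraries, 3 came from Dnmt3A WT/WT mice and 3 from Dnmt3A KO/KO mice, and the question was how loss of this de novo DNA methyltransferase alters the transcriptome of these cells. The labels number the samples of each genotype without saying whether they came from separate animals, so the p-values measure the spread between these samples. Counts summed to between 49694994 and 72742392 per library, of which between 14.1% and 15.5% fell on transposable element families.

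Dnmt3a itself fell in every KO/KO library. The gene (chromosome 12, positions 3806007 to 3914443, GRCm38) had 215, 193 and 188 CPM (counts scaled by library size) in the WT/WT libraries and 90.2, 104 and 99.5 CPM in the KO/KO libraries, a log2 fold change of -1.02 (SE 0.09, n = 3 per genotype, edgeR adjusted p = 0.000222). The files count whole genes, so the remaining reads do not show which exons they came from. Dnmt1, the maintenance methyltransferase, stood at 609 ± 45.6 CPM in WT/WT and 628 ± 69.4 CPM in KO/KO (SD, n = 3 each) and did not pass the test (edgeR adjusted p = 0.802).

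The genotypes differed widely. Of 21314 genes tested, 1776 were higher and 1368 lower in KO/KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 850 and 513 of these changed at least 2-fold. Among called genes with an average log2 CPM of at least 1, leaving out predicted and clone symbols, the largest rise was that of Tal1, a transcription factor of blood stem cells on chromosome 4 (115056426 to 115071755), from 0.114 ± 0.0407 to 10.5 ± 3.16 CPM (log2 fold change 6.50, SE 0.36). Cd2, a lymphocyte adhesion molecule, rose by 5.07 on the log2 scale (SE 0.48), the immunoglobulin family gene Igdcc3 by 4.93 (SE 0.22) and the X-linked homeobox gene Rhox5 by 4.84 (SE 0.32). Tnfrsf26, Hoxc9, Slc39a4, Prss45, the Notch ligand Dll4, the homeobox gene Hlx, Glmp and the histone deacetylase Hdac7 completed the 12 largest rises, with log2 fold changes from 4.64 down to 3.34. The largest falls included those of Tcea3 (log2 fold change -3.73, SE 0.37), Rspo1, Lhx8, Prtg, Igfbp6, Ccdc113, Lef1, Neurog3, Sfrp2, Crybg3 and Pik3ap1 (-2.82, SE 0.35). Among these, Prtg fell from 73.4 ± 6.95 to 7.17 ± 2.33 CPM and Lef1, a transcription factor of Wnt signalling, from 15.7 ± 1.48 to 1.88 ± 0.678 CPM (SD, n = 3 each). Without KO/KO replicate 1 the fall of Lhx8 was -4.67 and that of Crybg3 -3.85, and without WT/WT replicate 3 the rise of Slc39a4 was 4.62. For Glmp, 20.3% of the exon bases lie under exons of Tmem79 on the opposite strand, and the strand setting of the counting is not given in the sources used here. The counts of genes fell when a WT/WT library was left out, to 1083 higher and 652 lower without replicate 1, 814 and 560 without replicate 2, and 892 and 663 without replicate 3. In counts simulated for this comparison 9.82% of the calls were false, against the nominal 5%. The simulation changed 200 genes and gave both genotypes the same spread, so this share is not an error rate for the 3144 calls.

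**Figure D1:**
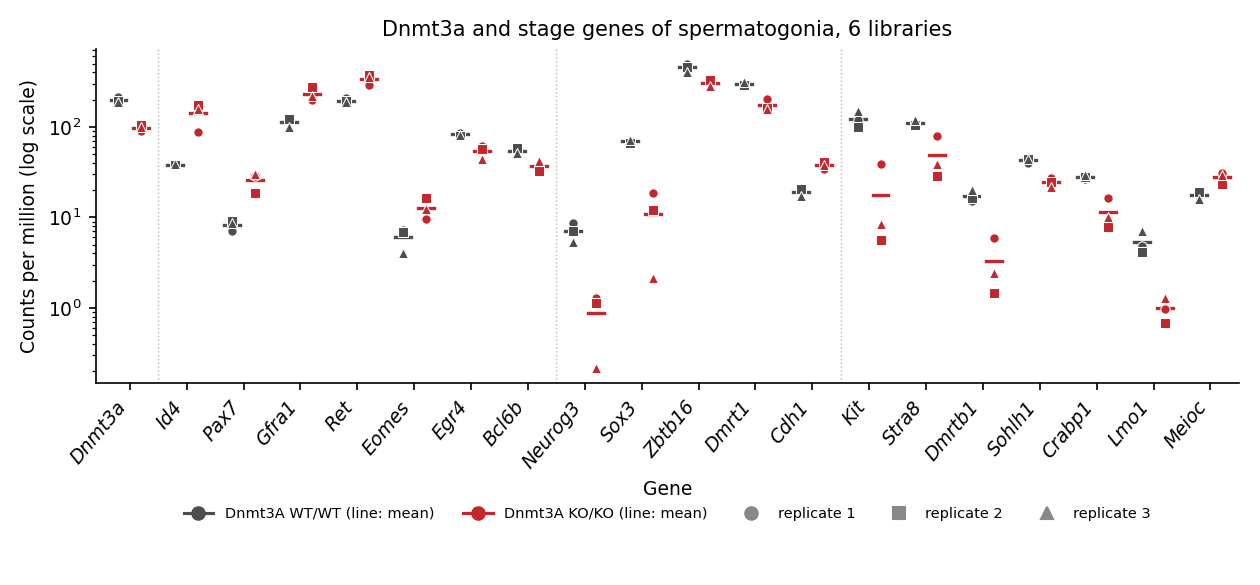
CPM (vertical axis, log scale) of Dnmt3a and 19 genes of spermatogonial stages in each of the 3 Dnmt3A WT/WT (grey) and 3 KO/KO (red) libraries; each point is 1 library, the point shape gives the replicate and short lines are group means. Dotted lines part Dnmt3a, stem cell enriched, progenitor and differentiating genes, and Kit stands at 38.6 CPM in KO/KO replicate 1 against 5.63 and 8.44 CPM in the other 2.

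Among genes enriched in spermatogonial stem cells, more rose than fell in KO/KO. Of 27 members tested, 15 rose and 3 fell (17 and 4 when adjusted over the list alone), with a median log2 fold change of 0.53. Id4, the gene whose reporter set the sorting gate, rose from 37.8 ± 0.78 to 141 ± 47.3 CPM, the satellite cell and stem cell factor Pax7 from 8.28 ± 1.02 to 25.7 ± 6.35 CPM, and Gfra1, the co-receptor for the niche factor GDNF, from 114 ± 12.2 to 229 ± 39.6 CPM (SD, n = 3 each). Egr4, a member of the same list, fell from 82.5 ± 4.02 to 54.2 ± 8.85 CPM, and Bcl6b and Pou3f1, both induced by GDNF, also fell. The list ranked higher than other genes (limma camera, preset correlation 0.01, adjusted p = 6.41e-06), but not with an estimated correlation (adjusted p = 0.400 with an estimated correlation). Of its members 9 rose and 1 fell without WT/WT replicate 2, and 8 rose without WT/WT replicate 3. The fall of Bcl6b lost its call without WT/WT replicate 2 (adjusted p = 0.0586) and that of Pou3f1 without each WT/WT replicate (adjusted p between 0.0962 and 0.108).

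GDNF and FGF signalling genes, 8 of whose tested members also belong to the stem cell list, included more rises than falls. Of 26 members 11 rose and 4 fell (14 and 4 when adjusted over the list alone). The receptor gene Ret rose from 195 ± 9.75 to 341 ± 45.7 CPM, and the feedback inhibitors Spry2 and Dusp4 rose by 2.32 (SE 0.22) and 2.30 (SE 0.28) on the log2 scale. Fgfr2 and Fgfr3, which encode FGF receptors, were among the 4 that fell, by 2.37 (SE 0.24) and 1.46 (SE 0.18) on the log2 scale. The list passed camera (adjusted p = 0.000394), and its adjusted p = 0.393 with an estimated correlation.

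Among genes listed here for progenitor and differentiating spermatogonia, the stages that follow the stem cell, more fell than rose in KO/KO. Whether listed members such as Zbtb16, Dmrt1, Foxo1 and Sall4 are confined to these stages was not tested. Of 16 progenitor genes 9 fell and 1, Cdh1, rose (11 and 2 when adjusted over the list alone). Neurog3, a transcription factor of progenitors, fell from 7.07 ± 1.69 to 0.883 ± 0.582 CPM, Zbtb16 from 456 ± 43.9 to 308 ± 25.4 CPM and Dmrt1 from 295 ± 17.4 to 174 ± 23.9 CPM. Sox3, named after its values were seen, fell by 2.67 on the log2 scale (SE 0.55), and by 3.28 without KO/KO replicate 1. Of 18 differentiating genes 7 fell and 2, Meioc and Ccnb3, rose (7 and 3 when adjusted over the list alone). Kit, the receptor that marks differentiating spermatogonia and also named after its values were seen, stood at 118, 98.9 and 150 CPM in WT/WT and at 38.6, 5.63 and 8.44 CPM in KO/KO (log2 fold change -2.81, SE 0.59, edgeR adjusted p = 0.0129). Its log2 fold change was -4.11 without KO/KO replicate 1. Dmrtb1 fell by 2.42 (3.15 without KO/KO replicate 1), Lmo1 by 2.44 and Sohlh1 by 0.82 on the log2 scale. Both lists passed camera (adjusted p = 0.000114 for progenitor and 0.00583 for differentiating genes), and neither did with an estimated correlation (adjusted p = 0.393 and 0.653). Of the progenitor genes 5 fell without WT/WT replicate 1 and 5 without WT/WT replicate 2, and 2 rose without KO/KO replicate 2. Meioc lost its call without WT/WT replicate 3 (adjusted p = 0.0594) and Ccnb3 without WT/WT replicate 2 (adjusted p = 0.0555).

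Among the lists of somatic and blood cell markers, that of endothelial cells had the most members past the test, 5 of 8. Next came 4 of 10 stromal and 3 of 6 macrophage markers, and the difference between lists was not tested. Of 8 endothelial markers tested, 5 rose and none fell (6 and 0 when adjusted over the list alone). Without each WT/WT replicate, and without KO/KO replicate 2 or 3, 4 rose. Sox18 was 1 of the 5 (log2 fold change 0.71, edgeR adjusted p = 0.0377), and it lost its call in each of these fits. Cdh5, the cadherin of endothelial junctions, rose from 6.53 ± 1.06 to 51.7 ± 15.2 CPM, Vwf from 1.75 ± 0.277 to 10.6 ± 1.83 CPM, and the VEGF receptor genes Flt1 and Kdr by 1.69 (SE 0.13) and 1.70 (SE 0.18) on the log2 scale. Pecam1 stood at 3.61 ± 1.14 and 4.04 ± 1.08 CPM in WT/WT and KO/KO and Tek at 3.04 ± 0.323 and 2.69 ± 0.366 CPM. The list passed camera (adjusted p = 1.39e-11), and its adjusted p = 0.0683 with an estimated correlation. Of 11 other abundant endothelial transcripts, listed after the results were seen, 2 rose and 1 fell (2 fell without KO/KO replicate 3), and that list did not pass camera (adjusted p = 0.859).

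Of 20 Sertoli cell markers, genes of the nurse cells of the tubule, 1 rose (1 and 0 when adjusted over the list alone), and that gene was Rhox5 (0.812 ± 0.385 to 23.5 ± 4.58 CPM). Clu, an abundant Sertoli transcript, was present in every library, at 309, 273 and 186 CPM in WT/WT and 194, 229 and 300 CPM in KO/KO. Of 8 peritubular myoid markers Smtn rose and Synpo2 fell, of 10 interstitial stromal markers 2 rose and 2 fell, and of 6 Leydig and steroidogenic markers none passed the test. When adjusted over the list alone, 1 myoid marker rose and 2 fell, 2 stromal markers rose and 2 fell, and 0 Leydig markers changed. Of 6 macrophage and leukocyte markers 2 rose and 1 fell, and of 3 erythroid markers 1 rose, at low counts, with the same numbers when adjusted over the list alone. Without any 1 WT/WT replicate the macrophage markers gave 1 rise and 0 falls and the erythroid markers 0. Without KO/KO replicate 2 or 3 the macrophage markers gave 1 rise, and the erythroid markers gave 2 without KO/KO replicate 1 and 0 without replicate 3. The stromal markers gave 1 rise and 1 fall without WT/WT replicate 1, 0 and 1 without replicate 2, 0 rises without replicate 3, and 1 rise without KO/KO replicate 1 or 3. Of the Leydig markers 2 fell without KO/KO replicate 3 and 1 without WT/WT replicate 1, of the Sertoli markers 2 rose without KO/KO replicate 1 or 2, and of the myoid markers 2 fell without WT/WT replicate 3. None of these lists passed camera (adjusted p = 0.170 for Sertoli, 0.932 for myoid, 0.533 for stromal, 0.305 for Leydig, 0.305 for macrophage and 0.519 for erythroid markers).

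**Figure D2:**
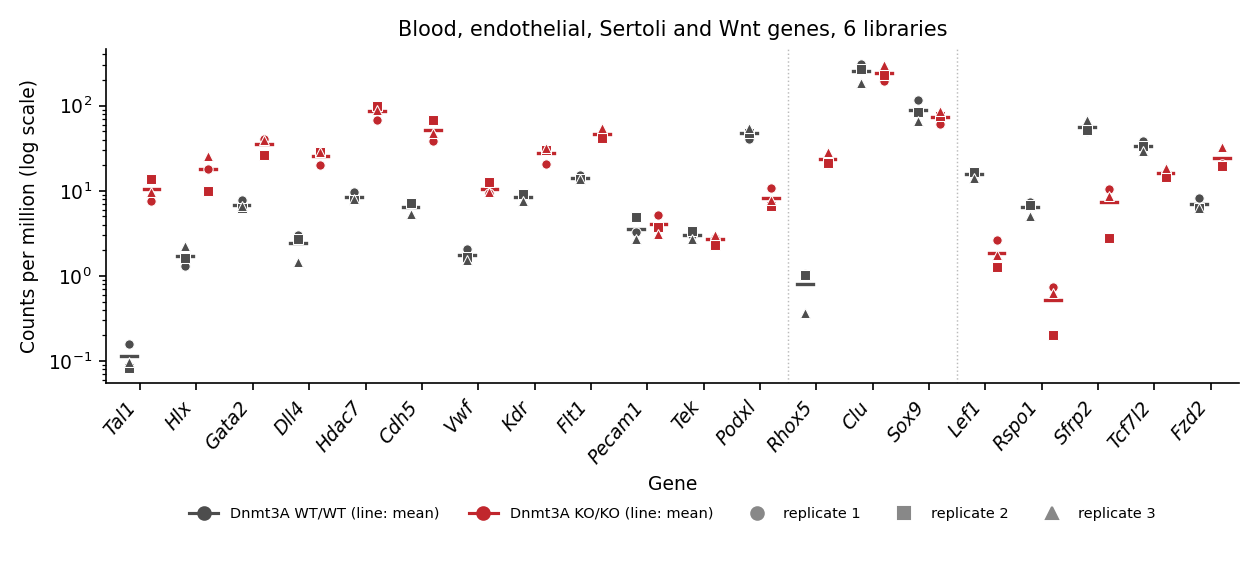
CPM (vertical axis, log scale) of 20 genes in each of the 3 Dnmt3A WT/WT (grey) and 3 KO/KO (red) libraries; points are libraries, shapes replicates and short lines group means. Dotted lines part blood and endothelial genes, Sertoli genes and Wnt genes; Cdh5 and Vwf lie higher in every KO/KO library, whereas Pecam1, Tek, Clu and Sox9 overlap between the genotypes.

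Hox genes, which set position along the body axis, included more rises than falls in KO/KO. Of 21 members tested 7 rose and 1 fell (8 and 2 when adjusted over the list alone). Hoxc9 rose from 0.312 ± 0.0873 to 5.53 ± 1.23 CPM and Hoxb13 from 0.518 ± 0.0255 to 2.03 ± 0.586 CPM. Hoxc10 had 0, 0 and 1 counts in the WT/WT libraries and 35, 70 and 119 in the KO/KO libraries. The list passed camera (adjusted p = 0.00120), and its adjusted p = 0.192 with an estimated correlation. Of its members 4 rose without WT/WT replicate 1 and 3 without WT/WT replicate 2.

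Among 44 imprinted genes 11 rose and 7 fell (17 and 10 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.175). Without WT/WT replicates 1, 2 and 3 the rises were 8, 4 and 6 and the falls 2, 1 and 2, and without KO/KO replicate 3 there were 3 falls. Zrsr1 rose from 36.3 ± 0.821 to 71.1 ± 12.9 CPM and Ndn from 9.21 ± 1.45 to 17.9 ± 1.65 CPM, whereas the paternally expressed gene Dlk1, named after its values were seen, fell from 20.3 ± 4.16 to 7.70 ± 2.78 CPM. Of 25 genes of the DNA methylation machinery 1, Kdm1b, rose and 3 fell, with the same numbers when adjusted over the list alone. The 5-methylcytosine oxidase gene Tet3 fell from 207 ± 17.4 to 76.0 ± 22.6 CPM and the H3K36 methyltransferase gene Nsd1 from 578 ± 6.23 to 410 ± 31.8 CPM. Of 25 piRNA and transposon silencing genes 3 rose, among them Spocd1 (log2 fold change 1.46, SE 0.26) and Gtsf1, and 2 fell, among them Pld6 (4 and 5 when adjusted over the list alone). Without KO/KO replicate 2 there were 2 rises in the methylation list, and without each WT/WT replicate and KO/KO replicates 1 and 3 there was 1 fall in the piRNA list. Neither list passed camera (adjusted p = 0.181 and 1.00).

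Of 22 retinoic acid pathway genes 3 rose and 4 fell (5 and 8 when adjusted over the list alone, camera adjusted p = 0.332), with Aldh1a3, a retinoic acid synthesis enzyme, at 3.74 ± 1.09 and 11.5 ± 2.06 CPM and Rxrg at 1.55 ± 0.238 and 0.229 ± 0.121 CPM. Of 16 pluripotency genes 2, Esrrb and Dppa4, rose and 4 fell, including Tbx3 and Pou5f1 (4 and 4 when adjusted over the list alone, camera adjusted p = 0.970). Of 26 meiotic genes 5 rose and 1, Sycp3, fell (6 and 1 when adjusted over the list alone, camera adjusted p = 0.127), and 3 rose without each WT/WT replicate. For Sycp3, 52.2% of the exon bases lie under Chpt1 on the opposite strand, and its call was lost without WT/WT replicate 2 (adjusted p = 0.0726) and without replicate 3 (adjusted p = 0.0522). Of 11 post-meiotic spermatid genes 3 rose and none fell, with Tnp1 at 0.408 ± 0.113 and 1.81 ± 0.258 CPM (3 and 1 when adjusted over the list alone, camera adjusted p = 0.0662), and 1 fell without KO/KO replicate 3. Immediate early and heat shock genes included more rises than falls, with 7 of 20 rising, among them Fos, Fosb and Ier3, and 1, the chaperonin gene Hspd1, falling (7 and 1 when adjusted over the list alone, camera adjusted p = 0.0662). Without WT/WT replicates 1, 2 and 3 the rises were 3, 3 and 5, and without KO/KO replicate 2 there were 2 falls. Hspd1 lost its call without WT/WT replicate 2 (adjusted p = 0.0987), WT/WT replicate 3 (adjusted p = 0.0795) and KO/KO replicate 3 (adjusted p = 0.0514).

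None of the 30 proliferation genes passed the test singly (0 and 0 when adjusted over the list alone), with a median log2 fold change of -0.19. Without KO/KO replicate 1 there were 3 lower, and without KO/KO replicate 2 there was 1 higher. The median was -0.01 without KO/KO replicate 2 and -0.11 without WT/WT replicate 3. The list passed camera (adjusted p = 0.0231), but not with an estimated correlation (adjusted p = 0.821), without KO/KO replicate 2 (adjusted p = 0.784) or without WT/WT replicate 3 (adjusted p = 0.175). Of 13 mitochondrially encoded genes 4 fell (7 when adjusted over the list alone), with mt-Co1 at 5412 ± 231 CPM in WT/WT and 3560 ± 576 CPM in KO/KO (camera adjusted p = 0.00860, and adjusted p = 0.736 with an estimated correlation). This list lost its call without KO/KO replicate 2 (adjusted p = 0.0815), and 1 member fell without each WT/WT replicate. Of 18 p53 response genes 1, Sesn2, rose and of 19 interferon response genes 1, Rsad2, rose (the same numbers when adjusted over the list alone, camera adjusted p = 1.00 and 0.807). Sesn2 lost its call without WT/WT replicate 2 (adjusted p = 0.0619) and replicate 3 (adjusted p = 0.0688), and 1 p53 gene fell without KO/KO replicate 1 or 2. Without KO/KO replicate 1 there were 4 interferon genes higher, and without KO/KO replicate 2 or 3 there was 1 lower. For 3 of these lists the signs differ: pluripotency genes had a median log2 fold change of 0.17 and a mean of -0.19, piRNA genes a median of 0.01 with a camera direction of lower, and p53 genes a median of -0.01 with a camera direction of higher. None of the 22 clustered beta protocadherins had enough counts to be tested.

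**Figure D3:**
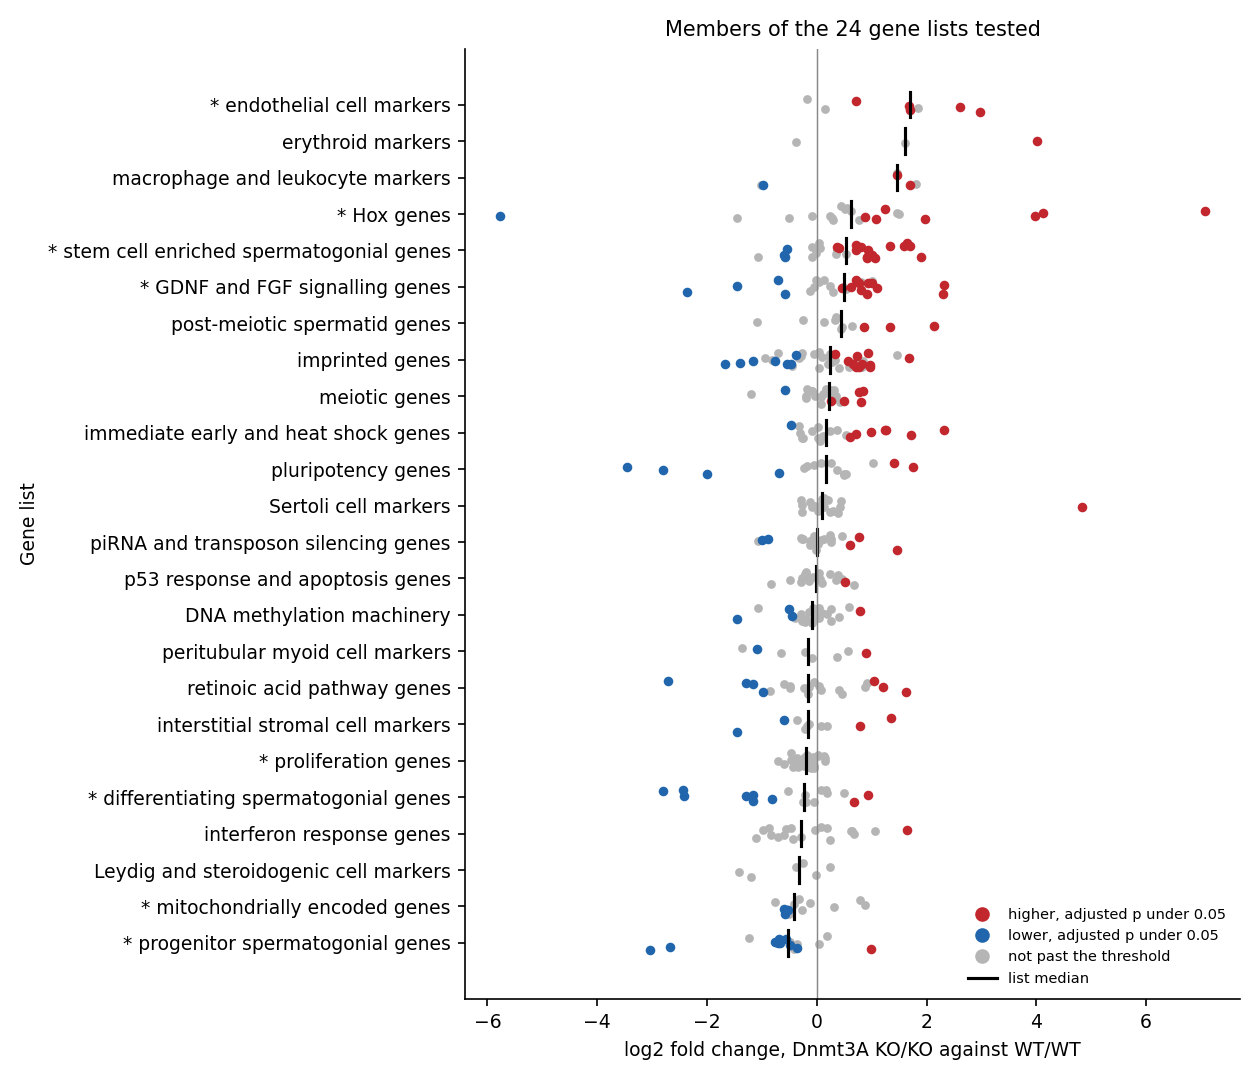
Log2 fold change of Dnmt3A KO/KO against WT/WT (horizontal axis) for each tested member of the 24 gene lists (vertical axis), ordered by list median (black line); red and blue points passed the edgeR test upward and downward, grey points did not, and an asterisk marks the 8 lists past camera with the preset correlation. The point furthest right among the Hox genes, Hoxc10, has 0 or 1 counts in each WT/WT library, so its fitted value depends on the prior count.

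Transposable element families, repeats that DNA methylation helps to silence, rarely passed the test. Of 1159 families tested together with the genes, none was higher and 1, IAPEy-int, an intracisternal A particle family, was lower in KO/KO. It stood at 35.1, 37.2 and 35.8 CPM in WT/WT and at 9.27, 5.90 and 5.81 CPM in KO/KO (log2 fold change -2.37, SE 0.18, edgeR p adjusted over the families = 0.000173). The MERVL-int and L1MdA_I families had log2 fold changes of -0.01 and -0.08. IAPEz-int (0.20, edgeR adjusted p = 0.575) and L1MdTf_III (0.27, edgeR adjusted p = 0.552) lay higher in every KO/KO library without passing the test. Of the families, 106 lay higher and 66 lower in every KO/KO library than in any WT/WT library, 14.8% against 10% by chance. MMERVK10C-int, at 499 and 309 CPM, and ETnERV2-int, at 14.3 and 21.5 CPM in WT/WT and KO/KO, did not overlap between the genotypes (log2 fold changes -0.69 and 0.58, adjusted p = 0.207 and 0.467), and 74 families had an unadjusted p under 0.05. L1MdTf_I stood at 1935 CPM in KO/KO replicate 3 and between 858 and 964 CPM in the other 5 libraries. The number of families called rested on how they were fitted and over which rows p was adjusted, a choice made after the counts below had been seen. Adjusting the same fit over all rows gave 11 higher and 5 lower, fitting the families without the genes gave 15 and 12, and limma-voom gave 7 and 7, and each of these 3 called both MMERVK10C-int and ETnERV2-int. The robust fit without the genes called ETnERV2-int but not MMERVK10C-int, and the fit with the families' own totals called neither. Without KO/KO replicate 2 there were 1 higher and 3 lower.

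**Figure D4:**
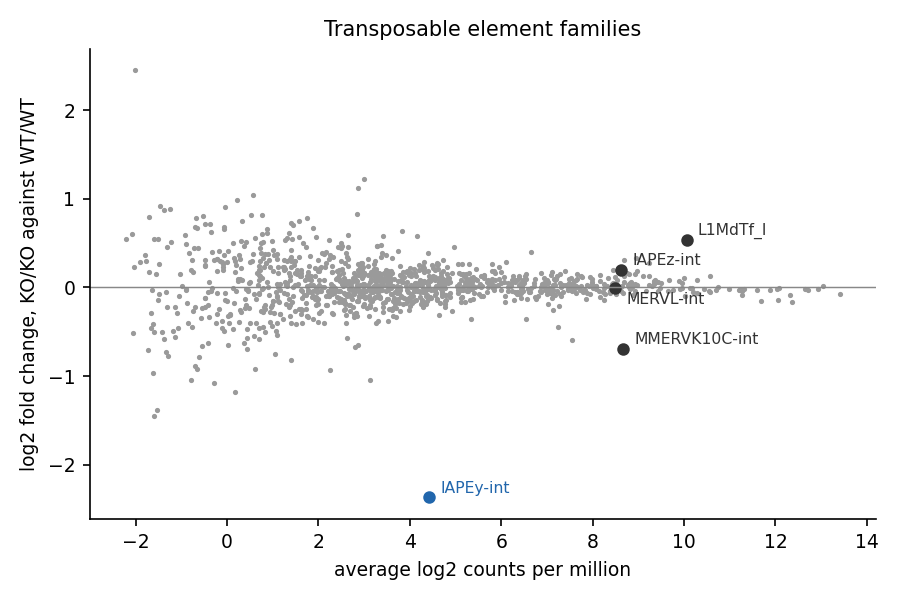
Log2 fold change of Dnmt3A KO/KO against WT/WT (vertical axis) against average log2 CPM (horizontal axis) for the 1159 transposable element families tested, each point being 1 family. IAPEy-int (blue, -2.37) is the family past the edgeR threshold after adjustment over the families, and L1MdTf_I, IAPEz-int, MERVL-int and MMERVK10C-int are named for reference.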

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

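The settings for the transposable element families, the fits of Dnmt3a with other filters, the fit with the families in the library size and the fit without the 5 most abundant gene rows were chosen after the data were seen. Of the 3144 genes called, 1206 remained called in the same direction in all 6 fits without 1 library. No called gene changed sign under any setting in which it was tested. The kept signs add little, since the genotypes did not overlap in CPM for 3131 of the 3144 genes. RLE and upper quartile factors, both filters, DESeq2 and limma-voom kept between 88.6% and 99.3% of the calls. The counts of higher and lower genes were 850 and 513 at a log2 fold change of at least 1, 2087 genes were lower at an adjusted p under 0.10, and without 1 library they ranged from 814 to 1985 higher and from 560 to 1380 lower, the low values coming without WT/WT replicate 2. No pairing by replicate number was visible in the expression values. Same-numbered deviations correlated at -0.09, 0.04 and 0.02, and not every sample correlated best with its own number. With so few samples this does not exclude a shared litter or day, on which the labels are silent. With the replicate block there were 1467 higher and 1107 lower genes. Dnmt3a kept its direction and its call in each of these fits.

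With an estimated correlation 0 of the 24 lists were called; adjusted p was 0.400 for stem cell enriched, 0.393 for progenitor, 0.653 for differentiating, 0.393 for GDNF and FGF, 0.192 for Hox, 0.821 for proliferation, 0.0683 for endothelial and 0.736 for mitochondrially encoded genes. By fry, which asks whether a list moves on balance, the adjusted p of differentiating (0.124), proliferation (0.457) and mitochondrial genes (0.260) missed the threshold, and that of meiotic (0.0451), post-meiotic (0.0320) and imprinted genes (0.0252) passed it. Without the filter the adjusted p was 0.00928 for immediate early and heat shock and 0.0491 for Sertoli genes, and with the filter at 1 CPM it was 0.0489 for post-meiotic genes. With the replicate block it was 0.0207 for immediate early genes, and the block changed no other list's call. Directions turned only for lists that were not called: pluripotency genes without the filter (0.924), piRNA genes without the filter (0.924), at 1 CPM (0.984), with the block (0.896), without the 5 most abundant rows (0.979) and by fry (0.935), p53 genes with upper quartile factors (0.991) and myoid genes at 1 CPM (0.984), and, in fits without 1 library, the same lists and interferon genes. Leaving out 1 library gave adjusted p from 0.0347 to 0.288 for meiotic, 0.0211 to 0.149 for post-meiotic, 0.781 to 0.985 for pluripotency, 0.417 to 0.985 for piRNA, 0.000376 to 0.784 for proliferation, 0.463 to 0.964 for p53, 0.318 to 0.985 for interferon, 0.0237 to 0.108 for immediate early, 0.0219 to 0.766 for Sertoli, 0.198 to 0.985 for myoid, 0.0116 to 0.543 for Leydig, 0.0237 to 0.766 for erythroid and 0.000376 to 0.0815 for mitochondrial genes. The log2 fold change of Pecam1 ranged from -0.0617 without KO replicate 1 to 0.436 without WT replicate 2, and the log2 fold change of Alas2 from -0.619 without KO replicate 3 to 0.0403 without WT replicate 3, neither passing the test.

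For the transposable element families, 11 were higher and 5 lower with adjustment over all rows. Fitted without the genes there were 15 and 12, with the robust option 15 and 9, by limma-voom 7 and 7, and with the families' own totals 5 and 4. With the replicate block there were 0 higher and 1 lower. Without 1 library there were 0 to 1 higher and 1 to 3 lower, and IAPEy-int was called in every setting. The cause of these changes was not tested. Whether the lower gene counts without a WT/WT library came from fewer samples in the less variable group was not tested either. Depth limits low genes such as Hoxc10 to statements on counts.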

Other observations

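The gene groups in the first 2 paragraphs were listed after the results were seen, some of them because a member ranked among the largest changes, so their p-values are not independent evidence. Transcription factors of blood and endothelial cells included large changes in both directions. Of 22 tested, 7 rose and 3 fell (9 and 3 when adjusted over the list alone), and 4 rose and 1 fell without WT/WT replicate 2. Gata2 rose from 6.88 ± 0.817 to 35.6 ± 8.21 CPM and Hlx from 1.72 ± 0.472 to 17.9 ± 7.93 CPM, beside Tal1, whereas Fli1, an ETS factor of the same lineages, fell from 1.61 ± 0.927 to 0.156 ± 0.0143 CPM (SD, n = 3 each). The list had a camera adjusted p = 0.000147, and adjusted p = 0.0514 with an estimated correlation. Of 13 Rhox cluster genes on the X chromosome 3 rose (6 when adjusted over the list alone, and 5 of those tested without KO/KO replicate 2), with Rhox1 at 6.73 ± 0.512 and 12.8 ± 1.46 CPM beside Rhox5 (camera adjusted p = 0.000125, and adjusted p = 0.226 with an estimated correlation). The third, Rhox4b, lost its call without WT/WT replicate 2 (adjusted p = 0.0606) and replicate 3 (adjusted p = 0.0561).

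More Wnt pathway genes fell than rose. Of 31 tested, 11 fell, 2 rose and 18 did not pass the test (14 and 3 when adjusted over the list alone), and 6 fell without WT/WT replicate 3. The ligand enhancer Rspo1 fell to 0.525 ± 0.284 CPM in KO/KO (edgeR adjusted p = 0.000638), Sfrp2, a secreted Wnt antagonist, from 56.5 ± 10.1 to 7.31 ± 4.01 CPM, and Tcf7l2 from 33.5 ± 4.52 to 16.2 ± 2.12 CPM, while the receptor gene Fzd2 rose from 6.97 ± 1.16 to 24.2 ± 7.27 CPM (SD, n = 3 each). The list had a camera adjusted p = 2.36e-05, and adjusted p = 0.0514 with an estimated correlation. Of 22 striated muscle contractile genes 4 rose and 7 fell (7 and 8 when adjusted over the list alone), with Ttn at 505 ± 143 and 164 ± 67.2 CPM (camera adjusted p = 0.121, direction lower, although the median log2 fold change was 0.37, and 0.59, 0.07 and 0.06 without WT/WT replicate 1, WT/WT replicate 2 and KO/KO replicate 2). Of 22 Notch pathway genes 6 rose and 2 fell (6 and 3 when adjusted over the list alone, camera adjusted p = 0.433, direction higher, median log2 fold change -0.03, above 0 without WT/WT replicate 1 and KO/KO replicates 1 and 3). Without WT/WT replicate 2, 3 Notch genes rose and 1 fell, and 1 fell without WT/WT replicate 1 or 3. Of 8 Y-linked genes none passed the test (none when adjusted over the list alone, camera adjusted p = 0.725), and 1 rose without KO/KO replicate 3.

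Of the tests below, those of the Sertoli markers, of the gain in CPM of endothelial transcripts and of the shares of stem and differentiating cells were chosen after the results were seen. With 3 samples per genotype there are 10 splits, too few for a share under 0.05. The genotypes gave 1776 higher and 1368 lower genes, and the highest of the other splits gave 0 in either direction. In each case 1 of the 10 splits gave as many. Every other split mixes the genotypes, so the genotype difference adds to its spread, and its 0 does not measure calls by chance. For the transposable element families the genotypes gave 0 higher and 1 lower, and the highest of the other splits gave 0; 10 and 1 of the 10 splits gave as many.

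The first pattern is the rise of stem cell enriched genes with the fall of genes listed as progenitor or differentiating. A larger share of stem cells in the KO/KO sort may produce it without a change within cells. That 18 called genes, among them Tal1 and Igdcc3, rose beyond the largest rise of the stem cell list excludes nothing, since they were picked for their rise and several lie near 0 CPM in WT/WT. Of 27 stem cell genes 3 fell (Bcl6b, Egr4 and Pou3f1), and of 18 differentiating genes 2 rose (Meioc and Ccnb3), opposite to such a share. If no gene changed, 0.0994 and 0.0663 such calls would arise by chance (1-sided binomial p = 0.000137 and 0.00199, members taken as independent). This test cannot decide on the share, since genes did change: 1368 of all 21314 were called lower and 1776 higher. The members also had estimated correlations of 0.258 and 0.372, the lists may misplace genes, and the criterion replaced an earlier one. The folds of Bcl6b, Egr4, Pou3f1, Meioc and Ccnb3 kept their signs in all 6 fits without 1 library, which the criterion required of them. Calls were lost for Bcl6b (-0.53 without WT/WT replicate 2), Pou3f1 (-0.54, -0.58 and -0.53 without each WT/WT replicate), Meioc (0.61 without WT/WT replicate 3) and Ccnb3 (0.86 without WT/WT replicate 2). A larger share as the whole cause or part of it, and a change within the cells after loss of Dnmt3a, stay open as untested hypotheses. Counts from single cells of the same stage in both genotypes would decide between them.

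The second pattern is the rise of markers of other cell types, which cells of those types in the KO/KO sort may bring. For Rhox5 the tables argue against a larger share of Sertoli cells in the KO/KO sort. The other 19 Sertoli markers had a median log2 fold change of 0.10 against 4.84 for Rhox5, and none of them was called. These values do not show which cells expressed Rhox5, since the Sertoli transcript Clu was present in every library of both genotypes. For Cdh5, Vwf, Kdr and Flt1, the called markers rising at least 2-fold, the tables argue against endothelial cells as the whole source. Part of the contrast comes from picking these markers for their rise. Of 20 other abundant endothelial transcripts, 9 had too few counts to be tested. The median gain over all 20 was 0.0220 CPM (quartiles -0.0719 and 0.430), against at least 8.86 CPM for each of these markers. The 11 tested had a median log2 fold change of 0.38 (0.14 and 0.08 without WT/WT replicates 1 and 3, 0.20 and 0.22 without KO/KO replicates 2 and 3), whose interquartile half-width of 0.62 left the comparison open by itself, with Cd93 and Eng rising and Podxl falling; Cd93 gained 19.9 CPM, more than Vwf and Kdr, Eng 3.31 CPM, and Podxl lost 39.2 CPM. Expression of these markers in the sorted germ cells stays open as an untested hypothesis. Staining of sorted cells for CDH5 together with a germ cell protein would test it for Cdh5 alone.

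The third pattern is the breadth of the genotype difference, part of which DNA carried along with the targeted Dnmt3a allele might cause near the gene. Within 20 Mb of Dnmt3a 17.4% of 69 tested genes were called (exact 95% interval 9.32% to 28.4%), and elsewhere 17.7% of 15530 genes (Fisher's exact test, two-sided, p = 1.00). The upper limit exceeds 1.5 times the share elsewhere, so the interval is too wide to exclude a local excess of that size. The test covers the 73.2% of tested genes that had a position, and it says nothing on calls far from Dnmt3a.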
